A study of Mus musculus with 6 samples.

How the data were processed

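Gene expression was measured with a whole-transcript microarray in 6 RNA samples labelled as mouse follicular B cells. Of these, 3 came from control mice and 3 from transgenic mice. The control mice carried a conditional miR-17 to miR-92 allele on both chromosomes and no Cre recombinase, although the sample titles call them wild type. The transgenic mice carried the same allele and CD19-Cre, which turns the allele on in B lineage cells. According to the series text, the B cells were enriched by magnetic depletion of cells bearing CD5, CD43 or CD93, with a purity above 95% by flow cytometry. Total RNA was amplified, fragmented and biotin-labelled with NuGEN kits, per the labels' protocols.

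The deposited values are on the log2 scale and were made by the authors with robust multi-array averaging (RMA), per the submitters' processing notes; the software and its version are not given in the sources used here. RMA subtracts background, equalises the intensity distributions of the arrays and combines the probes of a probe set into 1 value, so a change shared by most transcripts would be removed and fold changes of dim probe sets are compressed. The values are rounded to 2 decimals in the table, and carry no detection calls. Array medians lay between 5.89 and 5.99, and the smallest and largest single values were 2.55 and 14.06. The number of arrays, 3 per group, limits the precision. The labels do not say whether each array stands for 1 mouse or a pool, so p-values measure only the spread between these samples, which may be technical.

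The table held 28853 probe sets. Gene symbols came from the platform annotation, which named 23410 of them; 21789 had 1 symbol, 1621 had several and 5443 had none. Entrez identifiers of 21698 probe sets with 1 symbol matched the RefSeq gene table of mouse assembly GRCm38.p6, which changed 0 symbols and was otherwise used only for the chromosome of a gene. Probe sets with several symbols or none were left out of the gene table. For the 999 genes with several probe sets, the probe set with the highest mean over the 6 arrays stood for the gene, which left 19938 genes. No genome sequence was used. The planned test of genes with seed matches in their 3′ untranslated regions was not run, because untranslated region sequences were not used here; target lists took its place.

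Transgenic and control arrays were compared gene by gene with limma 3.58.1 in R 4.3.3 (lmFit and eBayes without trend or block, all 6 arrays), and a gene was called changed at a Benjamini-Hochberg adjusted p under 0.05 over the 19938 genes. Fold changes are transgenic over control; errors of group means are SD and errors of log2 fold changes are limma's moderated standard errors. With 3 against 3 arrays an exact two-sided permutation test of a single value cannot give a p below 0.1. Gene lists were tested with limma's camera at a preset inter-gene correlation of 0.01, adjusted over the 37 lists with at least 5 measured genes, and camera with an estimated correlation and fry were run beside it. The design, the 38 lists (23 by function and 15 of cell type or sex markers, from general knowledge), the rule for named genes and the alternative settings were fixed before the data were examined.

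The rule named the 12 highest and the 12 lowest log2 fold changes among called genes whose groups did not overlap, leaving out 5 predicted-gene, olfactory or clone symbols. It also named the measured members of the transgene list, 9 published miR-17 to miR-92 targets (Pten, Bcl2l11, Phlpp2, Cyld, Tnfaip3, Traf3, Rnf11, Itch and Tax1bp1), and up to 4 members of each list with the lowest p. Cd19, Pten, Traf3 and the ROSA26 locus had no probe set named by the annotation and were not analysed here. A further 3 panels of genes (paralogous clusters, X genes that escape inactivation, red pulp macrophage genes) were written after the calls were seen. 

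The gene and list tests were tested on simulated arrays with the measured means of the 19938 genes, 200 of them changed, in 20 simulations. The simulated spreads were limma's moderated SDs, which draw extreme SDs towards a common value, rather than the measured ones. At an added log2 difference of 0.5 the test recovered 69.3% of the changed genes, at 1 it recovered 99.9% and at 1.5 it recovered 100%; 6.35% of calls were false, and simulations without change gave 0.2 calls on average. Simulated lists of 22 genes were called in 1 of 20 simulations with no shift, and in 20 of 20 at shifts of 0.2 and 0.4. Each simulated list was scored on its own, at an unadjusted camera p under 0.05. Lists of the data were called after adjustment over all tested lists, a stricter rule, so these rates do not describe the list calls below. The simulated genes varied independently, unlike real genes.

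The alternative settings were a second quantile normalization, median centring of arrays, an intensity trend, robust eBayes, array weights, 2 filters on dim probe sets (mean above the median of all probe sets, or a mean log2 value of at least 6), the mean of all probe sets of a gene, each array left out, the replicate number as a block, all probe sets, 2 other thresholds (adjusted p under 0.1, or an absolute log2 fold change of at least 0.5 besides) and 3 other list tests. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.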

Results

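RNA of preparations labelled follicular B cells, mature B cells that recirculate through lymphoid follicles, was profiled in 3 control and 3 transgenic samples. The share of other B cell subsets left after the depletion was not measured here. The miR-17 to miR-92 cluster encodes several microRNAs from 1 primary transcript. In the transgenic mice CD19-Cre turned on its conditional allele, which lay on both chromosomes. The comparison therefore asks which transcripts differ between these preparations when the cluster is turned on together with Cre. The controls carried no Cre, so effects of the cluster and of Cre cannot be told apart here. Pearson correlations across all probe sets ranged from 0.986 to 0.995 between control arrays, from 0.986 to 0.996 between transgenic arrays and from 0.981 to 0.994 between the groups, and no pair of arrays was identical. Control 1 correlated best with transgenic 2 (0.991, against 0.987 and 0.986 with the other controls), and transgenic 2 best with control 1 (against 0.986 and 0.989 with the other transgenic arrays). Control 1 and transgenic 2 had the 2 highest scores on the second principal component (20.3 and 5.80, against -14.3 to -0.45 for the other 4 arrays), which held 25.3% of the variance.

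The microRNA cluster itself, on chromosome 14, was measured first as a check of the labels. Of the 5 probe sets named for a single microRNA of the cluster, 4 were higher in the transgenic arrays. Mir19b-1 rose 3.06-fold, from 8.73 ± 0.107 to 10.34 ± 0.0529 log2 units (SD, n = 3 per group; limma adjusted p = 0.000233). Mir18 rose 2.93-fold (log2 fold change 1.55, SE 0.101, adjusted p = 0.0004), Mir19a 2.52-fold (1.33, SE 0.110, adjusted p = 0.0017) and Mir17 2.42-fold (1.27, SE 0.160, adjusted p = 0.0112). Mir20a stood 1.79-fold above control with an adjusted p of 0.0530, which did not pass. Each of these 5 probe sets had its 3 transgenic values above its 3 control values (exact two-sided permutation p = 0.1, the smallest possible). A probe set for the host transcript alone, Mir17hg, differed by -0.03 (95% interval -0.33 to 0.27), with overlapping groups. Mir17 lost its call without transgenic replicate 3 (1.23, adjusted p = 0.0501) and when all probe sets were tested together (limma adjusted p = 0.0698). Left out together, the pair of control 1 and transgenic 2, an alternative chosen after seeing the data, took Mir19a to an adjusted p of 0.0660 and Mir17 to 0.0885. The array was hybridised with cDNA made from total RNA, and mature microRNA was not measured separately.

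**Figure D1:**
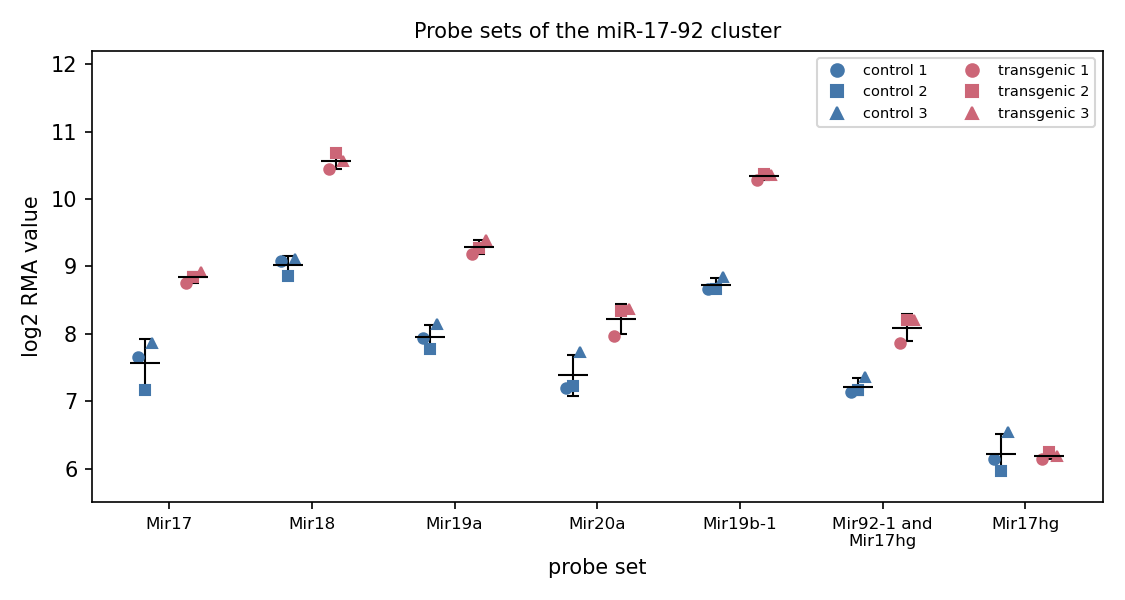
Log2 RMA values (vertical axis) of 7 probe sets of the miR-17 to miR-92 cluster (horizontal axis) in the 3 control and 3 transgenic arrays; points are arrays, horizontal bars group means and whiskers 1 SD. Transgenic values lie above control values for all probe sets except that of the host transcript Mir17hg alone, where the groups overlap.

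Across the transcriptome, 158 of 19938 genes changed, 123 higher and 35 lower in the transgenic arrays. The higher genes were led by the Y-linked Kdm5d, followed by transcripts of macrophages and the microRNAs, and the lower ones by Xist and Il9r. An absolute log2 fold change of at least 1 was reached by 37 of them, 34 higher and 3 lower. All 158 had groups that did not overlap, as had 2955 genes in all (14.8%, where chance gives 10%). The count depended on single arrays: it was 16 without control replicate 2, 42 without transgenic replicate 1, 42 without transgenic replicate 3 and 94 without control replicate 3. It fell to 12 when all 28853 probe sets were tested together, to 72 with arrays centred on their medians, and to 7 without the pair of control 1 and transgenic 2, whereas 392 genes passed with that pair as a block (both chosen after seeing the data). Among the 42 called genes named in the text, 12 kept their call whichever array was left out: Mir19b-1, Mir18, Mir19a, Cd5l, Vcam1, Csf1r, Trf, Treml4, Bhlhe41, Dtx1, Il9r and Xist. Of the 42, 28 lost their call without control replicate 2, 13 without control replicate 3 and 8 without control replicate 1. Without transgenic replicates 1, 2 and 3 the losses were 20, 11 and 21. The sign of the fold change stayed, which groups without overlap fix in advance when arrays are left out.

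Genes of the sex chromosomes separated the groups. Xist, the X-encoded RNA that silences 1 X chromosome in female cells, fell by 5.21 log2 units, from 10.49 ± 0.308 in controls to 5.28 ± 0.741 in transgenic arrays (SD, n = 3; limma adjusted p = 0.000271). Kdm5d, a Y-linked histone demethylase, was 6.93-fold higher (log2 fold change 2.79, SE 0.481, adjusted p = 0.0353). The Y-linked genes Uty (3.20, SE 0.638, adjusted p = 0.0638) and Eif2s3y (4.06, SE 0.942, adjusted p = 0.117) did not pass. Control 3 lay apart from the other controls, with Eif2s3y at 8.12 against 3.70 and 3.96 and Kdm5d at 6.97 against 4.95 and 4.66. Control 3 nevertheless had Xist at 10.44. Of the 4 measured members of the sex-linked list, 1 rose and 1 fell over all genes, and 3 rose and 1 fell adjusted over the list alone. Sex-linked transcripts and genotype thus moved together in these arrays, which applies to every gene group below. Of the 158 called genes, 6 lay on the X chromosome and 1 on the Y chromosome, and the median log2 fold change of the 739 X-linked genes was -0.0033. Kdm5d missed the threshold with median centring (adjusted p = 0.0554) and in 5 of the 6 fits that left out 1 array, with its lowest log2 fold change, 2.36, without control replicate 2 (adjusted p = 0.154). Without control replicate 3 the log2 fold changes were 3.52 for Kdm5d, 4.17 for Uty and 5.49 for Eif2s3y, and all 3 genes passed (limma adjusted p = 4.29e-06, 4.27e-06 and 3.01e-06).

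Macrophage genes were the cell type list with the most called members. In the monocyte and macrophage list 9 of 22 measured genes were higher and 0 lower, or 12 and 0 adjusted over the list alone, with a median log2 fold change of 0.40 (camera adjusted p = 2.98e-12; adjusted p = 0.139 with an estimated correlation). Csf1r, the receptor for macrophage colony-stimulating factor, rose 2.55-fold (8.18 ± 0.260 to 9.53 ± 0.133 log2 units, SD, n = 3; limma adjusted p = 0.0043). Vcam1, an adhesion molecule, rose 2.58-fold (log2 fold change 1.37, SE 0.148), Mrc1, the mannose receptor, 2.57-fold (1.36, SE 0.164), the heme oxygenase gene Hmox1 2.57-fold (1.36, SE 0.190) and Adgre1, an adhesion receptor of macrophages, 2.28-fold (1.19, SE 0.140). Outside the list, the highest fold changes included Cd5l, a secreted macrophage protein (1.77, SE 0.167, adjusted p = 0.0038), the C-type lectin Clec4n (1.64, SE 0.219) and the phagocytic receptor Mertk (1.38, SE 0.224). Control 3 had the highest Cd5l, Csf1r and Adgre1 of the controls, at 6.66, 8.46 and 7.43. The call of Adgre1 was lost without control replicate 2 (adjusted p = 0.0760). Mertk lost its call with median centring (adjusted p = 0.0574) and in 5 of the 6 fits that left out 1 array. Clec4n and Hmox1 each lost theirs in 2 of these fits, and Mrc1 in 1. When all probe sets were tested together, every called member of the list lost its call, as did Clec4n and Mertk, while Cd5l kept it.

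Of other blood cells, 2 erythroid and 2 dendritic cell genes also rose. In the erythroid list 2 of 15 measured genes rose, the carbonic anhydrase Car1 (2.58-fold, log2 fold change 1.37, SE 0.218, adjusted p = 0.0280) and the erythroid membrane protein Ermap (1.82-fold, 0.86, SE 0.156, adjusted p = 0.0418). Adjusted over the list alone 11 rose, and all 15 fold changes were positive with a median of 0.75 (camera adjusted p = 2.98e-12; adjusted p = 0.497 with an estimated correlation, and 0.188 with fry). Median centring ended the calls of Car1 (adjusted p = 0.0507) and Ermap (0.112). Of the 6 fits that left out 1 array, Car1 lost its call in 4 and Ermap in 5. In the dendritic cell list 2 of 13 rose, the lectin receptor Clec9a (1.05, SE 0.145) and the chemokine receptor Xcr1 (0.65, SE 0.105), or 4 adjusted over the list alone (median 0.20, camera adjusted p = 0.0015; adjusted p = 0.509 with an estimated correlation). The platelet and megakaryocyte list shifted upwards with 0 of 13 genes called, and 5 higher and 1 lower adjusted over the list alone (median 0.27, camera adjusted p = 0.0020; adjusted p = 0.507 with an estimated correlation). No member of the T cell (19 measured), NK cell (12), neutrophil (15) or stromal and endothelial (16) lists passed over all genes, and adjusted over the list alone 2 T cell genes were higher and 1 NK cell gene lower. Their camera adjusted p were 0.184, 0.514, 0.620 and 0.512.

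**Figure D2:**
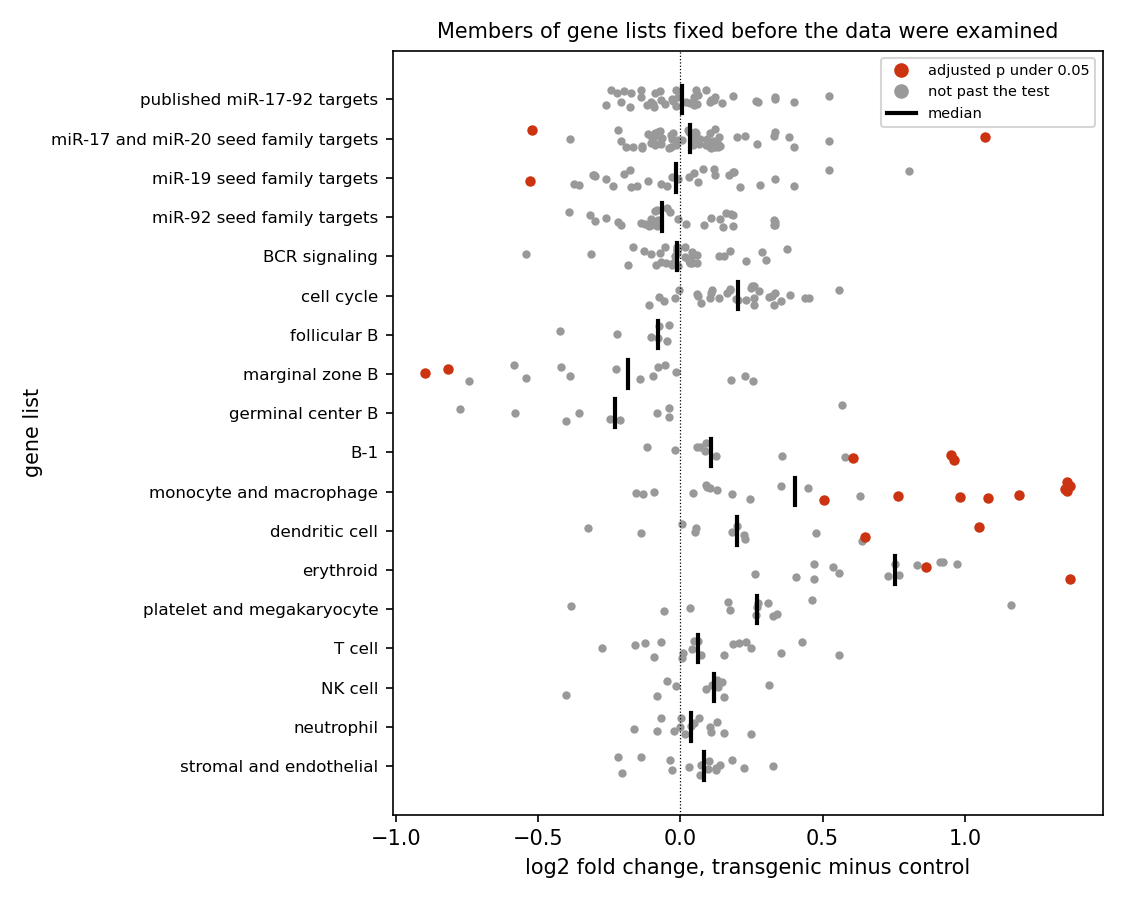
Log2 fold changes, transgenic minus control (horizontal axis), of the measured members of 18 gene lists (vertical axis); each point is a gene, red where its limma adjusted p was under 0.05, and black bars are medians. The macrophage and erythroid medians lie at 0.40 and 0.75, the marginal zone median at -0.18, and the median of the published targets at 0.01.

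In the marker lists of B cell subsets, 2 marginal zone genes fell and 3 B-1 genes rose. Which cells these transcripts came from was not tested. The marginal zone list had 2 of 16 genes called, both lower, or 7 lower and 1 higher adjusted over the list alone, and a median of -0.18 (camera adjusted p = 3.26e-06; adjusted p = 0.276 with an estimated correlation). Dtx1, a ubiquitin ligase induced by Notch2, was 1.76-fold lower (9.77 ± 0.0603 to 8.95 ± 0.104 log2 units, SD, n = 3; limma adjusted p = 0.0079), and the membrane protein gene Myof was 1.86-fold lower (-0.90, SE 0.109, adjusted p = 0.0109). The Notch target Hes1 stood at -0.74 (adjusted p = 0.0564) and the chemokine receptor Ackr3 at -0.58 (0.0638), both short of the threshold. The B-1 list had 3 of 12 genes higher, or 4 adjusted over the list alone (median 0.11, camera adjusted p = 0.000111; adjusted p = 0.276 with an estimated correlation). They were the transcription factor Bhlhe41 (1.93-fold, log2 fold change 0.95, SE 0.0928, adjusted p = 0.0043), the basement membrane gene Nid1 (0.96, SE 0.113, adjusted p = 0.0104) and the interleukin-5 receptor gene Il5ra (0.61, SE 0.110, adjusted p = 0.0426), of which Il5ra lost its call whichever array was left out, and with median centring (0.139). In the germinal center list 0 of 10 genes passed, and 3 were lower and 1 higher adjusted over the list alone, with a median of -0.23 (camera adjusted p = 0.0038; adjusted p = 0.579 with an estimated correlation); Rgs13, a regulator of G protein signaling, stood at -0.77 (adjusted p = 0.0547). All 7 measured follicular genes were negative, with 0 called and a median of -0.08 (camera adjusted p = 0.0315; adjusted p = 0.437 with an estimated correlation). The follicular call was lost without control replicate 1 (0.0940), without transgenic replicate 1 (0.0614), and after renewed quantile normalization (0.250). The transitional (15 measured, 0 called) and plasma cell (13 measured, 0 called, 2 lower adjusted over the list alone) lists had camera adjusted p of 0.244 and 0.0671.

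Among the remaining lower genes, Il9r, the interleukin-9 receptor, showed the largest change after Xist. It fell from 8.92 ± 0.0551 to 7.32 ± 0.249 log2 units (SD, n = 3), 3.02-fold, with a limma adjusted p of 0.0010. Rgs18, a regulator of G protein signaling, was 2.01-fold lower (-1.01, SE 0.162, adjusted p = 0.0284). The adaptor gene Sh2d2a (-0.84, SE 0.114), the anthrax toxin receptor gene Antxr2 (-0.82, SE 0.123) and the small GTPase gene Rras2 (-0.78, SE 0.0903) were also lower. Ell3, Hook1, Mcoln2 and Epcam, which encode a transcription elongation factor, a microtubule linker, an endolysosomal channel and an adhesion molecule, had log2 fold changes of -0.74, -0.74, -0.74 and -0.73. Median centring ended the calls of Ell3 (adjusted p = 0.0591), Hook1 (0.0694), Mcoln2 (0.0554) and Rgs18 (0.0529). Of the 6 fits that left out 1 array, Hook1 and Mcoln2 lost their calls in 5. Ell3, Rgs18 and Antxr2 lost theirs in 4, Sh2d2a and Epcam in 3, and Rras2 in 1.

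**Figure D3:**
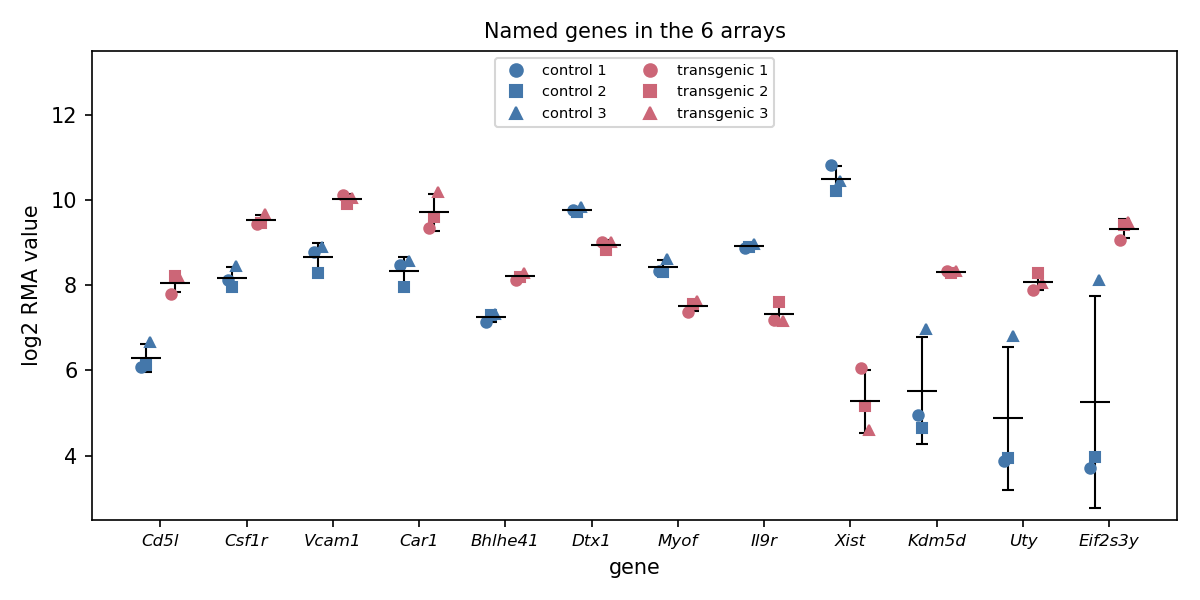
Log2 RMA values (vertical axis) of 12 named genes (horizontal axis) in the 3 control and 3 transgenic arrays; points are arrays, horizontal bars group means and whiskers 1 SD. Cd5l, Csf1r, Vcam1, Car1 and Bhlhe41 are higher and Dtx1, Myof, Il9r and Xist lower in all transgenic arrays, and control 3 lies between the other controls and the transgenic arrays for Kdm5d, Uty and Eif2s3y.

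Genes that the cluster is known to repress were not called as a group in the list tests of a shared direction. Only RNA was measured, so a change in translation alone would not be seen. Of 44 measured published miR-17 to miR-92 targets, 0 were called, also when adjusted over the list alone. Their median log2 fold change was 0.0067 and their mean 0.0214, against a downward direction in camera (adjusted p = 0.927). Bcl2l11, which encodes the pro-apoptotic protein BIM, differed by -0.0067 (95% interval -0.20 to 0.19), and Phlpp2, an AKT phosphatase, by -0.09 (-0.32 to 0.14). Among inhibitors of NF-kB signaling, Tnfaip3 stood at -0.26 (-0.47 to -0.05; limma adjusted p = 0.341), Cyld at -0.18 (-0.36 to 0.01), Tax1bp1 at -0.14 (-0.33 to 0.06), Itch at 0.05 (-0.15 to 0.25) and Rnf11 at 0.06 (-0.27 to 0.39). In the miR-17 and miR-20 family target list 1 of 64 genes was higher, the iron exporter Slc40a1 (1.07, SE 0.144, adjusted p = 0.0135), and 1 lower, the semaphorin Sema7a (-0.52, SE 0.0913, adjusted p = 0.0373). Adjusted over the list alone, 2 were higher and 2 lower (camera adjusted p = 0.604). In the miR-19 list 1 of 33 was lower, the small GTPase Rap2c (-0.53, SE 0.0897, adjusted p = 0.0333), and adjusted over the list alone 4 were higher and 1 lower (camera adjusted p = 0.620). In the miR-92 list 0 of 32 passed, also adjusted over the list alone (camera adjusted p = 0.620). Fry's mixed test, which counts changes in either direction, passed for the published, miR-17 and miR-20, miR-19 and miR-92 lists. Its adjusted p were 0.0122, 2.71e-05, 0.0015 and 0.000601. It was not particular to targets, since BCR signaling also passed (fry mixed adjusted p = 0.000689), while the cell cycle list did not (0.120). Sema7a and Rap2c lost their calls whichever array was left out.

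Proliferation genes shifted upwards as groups with camera at the preset correlation, without single calls. With fry, neither the cell cycle list (adjusted p = 0.475) nor the DNA replication list (0.614) was called. The cell cycle list had 0 of 33 genes called, 2 higher adjusted over the list alone, 28 positive fold changes and a median of 0.20 (camera adjusted p = 2.48e-06; adjusted p = 0.621 with an estimated correlation). Mki67, a marker of cycling cells, stood at 0.56 (adjusted p = 0.0516). The DNA replication and E2F list had 0 of 33 called and 4 higher adjusted over the list alone, with a median of 0.14 (camera adjusted p = 0.0039; adjusted p = 0.738 with an estimated correlation), and Uhrf1 stood at 0.52 (adjusted p = 0.0504). Array means of both lists followed the erythroid list in part: transgenic 2 was the lowest transgenic array in all 3 lists (erythroid 0.0042, cell cycle -0.087, DNA replication -0.054), transgenic 3 the highest (0.76, 0.29 and 0.26) and control 1 the lowest of all 6 (-0.66, -0.21 and -0.16), as deviations from the mean of all arrays. For cell cycle and DNA replication genes transgenic 2 lay within the range of the controls. The DNA replication list was not called without control replicate 1 (0.127) or without transgenic replicate 3 (0.402). The ribosome biogenesis and MYC list had 0 of 31 called, 0 adjusted over the list alone, and a median of -0.09 (camera adjusted p = 0.0019; adjusted p = 0.551 with an estimated correlation). The NF-kB list had 0 of 33 called, 0 adjusted over the list alone, and a median of -0.06 (camera adjusted p = 0.0099; adjusted p = 0.621 with an estimated correlation). Renewed quantile normalization ended the calls of both (adjusted p = 0.0762 and 0.131), and the 2 filters on dim probe sets ended that of NF-kB (0.102 and 0.108).

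Most signaling and metabolic lists were not called. In the PI3K-AKT-mTOR list 1 of 29 genes rose, the catalytic subunit Pik3cb (1.74-fold, log2 fold change 0.80, SE 0.139, adjusted p = 0.0360, and 0.0935 with median centring), and the list was not called (camera adjusted p = 0.525). Pik3cb also lost its call in 4 of the 6 fits that left out 1 array. The BCR signaling list had 0 of 37 called, also when adjusted over the list alone, and was not called (camera adjusted p = 0.747), with a median of -0.01 and a mean of 0.0019. No gene passed over all genes in the lists for FOXO targets (27 measured, camera adjusted p = 0.310), apoptosis (27, 0.604), B cell activation (36, 0.117), antigen presentation (17, 0.604), interferon-stimulated genes (31, 0.117), TGF-beta and BMP signaling (26, 0.0715) or p53 targets (23, 0.209). The same count of 0 held for glycolysis (20 measured, camera adjusted p = 0.334), the respiratory chain (32, 0.0715) and cholesterol and lipid synthesis (24, 0.244). It also held for microRNA processing and silencing (24, 0.1, and 0.0207 after renewed quantile normalization) and heat shock and unfolded protein genes (29, 0.0715). The respiratory chain list was called, downwards, with camera on ranks (adjusted p = 0.0355) and with the pair of control 1 and transgenic 2 as a block (0.0342). Adjusted over the list alone, 1 FOXO, 3 B cell activation, 3 TGF-beta, 1 cholesterol and 1 microRNA processing gene were higher. In the same way 2 B cell activation, 1 interferon-stimulated and 2 p53 genes were lower. In all, 13 of 37 lists were called with camera, 8 up and 5 down, among them the transgene list (3 of 5 measured genes higher, 4 adjusted over the list alone, camera adjusted p = 2.69e-10; adjusted p = 0.276 with an estimated correlation); with an estimated correlation 0 were called.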

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

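Both results below come from probe sets outside the gene table and were looked at because their signal lay above the control level in data that the gene comparison did not use; they entered only the check of the cluster or the fit of all probe sets. A probe set with no symbol in the annotation (ps10347335) was 1.02 log2 units higher in the transgenic arrays, at 8.11 ± 0.0800 against 7.09 ± 0.110 (SD, n = 3 per group; limma adjusted p = 0.0255 over all 28853 probe sets). It was the only 1 of the unnamed probe sets that passed, and 0 probe sets with several symbols did. The probe set shared by Mir92-1 and Mir17hg was 0.87 log2 units higher, or 1.83-fold, with all 3 transgenic values above the controls (limma adjusted p = 0.0701 over all probe sets, which did not pass).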

How the results depend on the processing

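The fits with the pair of control 1 and transgenic 2 as a block or left out, without X and Y genes, with the variance prior of all probe sets, and with robust eBayes on all probe sets were chosen after seeing the data. The 158 calls (123 higher, 35 lower) became 72 (55 and 17) with median centring, 12 (9 and 3) with all probe sets, 16 (12 and 4) with their variance prior alone, 61 (49 and 12) with robust eBayes on all probe sets, 263 (200 and 63) at an adjusted p under 0.1, 392 (270 and 122) with the pair as a block and 7 (4 and 3) without it. The lower count became 54 with quantile normalization and 59 with array weights. Leaving out 1 array gave 16 to 136 calls, 13 to 110 higher and 3 to 52 lower, with fewer arrays as part of the cause. The all-probe-set fit had a prior of 3.27 degrees of freedom against 5.38, and its prior alone gave 16. Unnamed probe sets varied more (1% of their SDs lay above 1.46, against 0.351 for genes), but whether they lowered the prior was not tested. For the other changes the cause was not tested either. All 158 genes kept their sign in the alternatives that tested them, although groups without overlap cannot change sign when arrays are left out. Centring moved the median log2 fold change by -0.0433.

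Lists called numbered 13 with camera, 0 with an estimated correlation and 6 with fry, and 12 to 17 with 1 array left out. With an estimated correlation the adjusted p were 0.276 for marginal zone, 0.276 for B-1, 0.139 for macrophage and 0.497 for erythroid genes. Fry ended the calls of the erythroid (adjusted p = 0.188), platelet (0.188), dendritic cell (0.1605) and ribosome biogenesis (0.299) lists. It also ended those of the cell cycle (0.475), germinal center (0.475), NF-kB (0.525) and DNA replication (0.614) lists, and called microRNA processing (0.0318). Both tests allow for correlation between members. Leaving out 1 array gave adjusted p of 5.96e-14 to 9.32e-11 (macrophage), 4.75e-08 to 0.00032 (marginal zone), 2.15e-18 to 2.55e-07 (erythroid), 2.85e-05 to 0.0025 (B-1) and 0.852 to 0.989 (published targets). Lists not called with all arrays were called without control replicate 1 (respiratory chain, 0.0078), control 2 (heat shock, 0.0078; TGF-beta, 0.0308), control 3 (heat shock, 0.0110; plasma cell, 0.0153), transgenic 1 (respiratory chain, 0.0178; heat shock, 0.0116) and transgenic 3 (respiratory chain, 0.0146; interferon, 0.0110; B cell activation, 0.0236; T cell, 0.0450; plasma cell, 0.0458). Of the 5 cluster probe sets 4 passed, 2 without the pair, and 3 to 5 with 1 array left out. Tested with all probe sets, Mir17 (limma adjusted p = 0.0698) and Mir20a (0.172) did not pass. The 60 genes named in the text gave 0 reversals (a sign change of a gene called in neither fit was not counted). For called genes, whose groups did not overlap, leaving out arrays could not reverse the sign. Over 12 alternatives 53 calls were lost and 39 gained. Over the 6 arrays left out in turn 101 were lost and 6 gained. With the replicate block 153 genes were called, 111 of them shared with the 158; same-numbered arrays had correlations of deviations of 0.0381, -0.254 and 0.382, and 2 of 6 arrays correlated best with their own number, so the numbers name samples only. The seed family test and its alternatives were not run. Without detection calls, signal over background cannot be judged for dim genes.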

Other observations

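All tests here were chosen after the results were seen, except the count of splits and the co-variation of marginal zone genes. In a panel of 26 red pulp macrophage genes, written after the calls were seen, 23 were higher and 0 lower in transgenic arrays, with a median log2 fold change of 1.07 (0.55 to 1.77). They included the iron exporter Slc40a1 (1.07), the transferrin gene Trf (1.07), the lectin-like receptor Treml4 (1.13) and the abundant cathepsin genes Ctsb (0.68, from 9.64 to 10.32 log2 units) and Ctsd (0.68). Spic, a transcription factor of these cells, stood at 0.93 and did not pass (limma adjusted p = 0.122). In a panel of paralogous miR-17 clusters 0 of 8 measured microRNA genes were called, with log2 fold changes of 0.06 to 0.34. Hemoglobin probe sets shared between genes differed by 0.28 to 0.42 (limma adjusted p = 0.540 to 0.564).

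With 3 arrays per group there are 10 splits, too few for a share under 0.05. The real split gave 158 genes and the highest of the other splits 0, so 1 of the 10 splits gave as many.

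Of 22 macrophage genes 9 were higher and 0 lower in transgenic arrays (adjusted p = 0.139 for the list with an estimated correlation), and a larger share of macrophages in those preparations may account for it. The depletion removed cells bearing CD5, CD43 or CD93, and its yield of macrophages was not measured here. Within groups, the 22 genes of the fixed list did not move together more than random lists (mean pairwise correlation 0.0382; random median 0.0343, with the central 95% up to 0.188), whereas the red pulp panel did (0.578; central 95% of random lists up to 0.383), consistent with a varying share of such cells, although its genes were picked with the calls in view (8 of its 26 genes are in the fixed list, and 15 of the other 18 were called). Such co-movement was not particular to these cells, since the erythroid list (0.770; central 95% of random lists up to 0.444) and the T cell list, with 0 called genes (0.296; up to 0.192), also showed it. Sex of the mice and an effect of the transgene or of Cre, direct or indirect and not tested here, stay open. Control 3 had intermediate Y-linked signal. For the called list genes it lay a median of 18.9% of the way from the other controls to the transgenic mean. No male control array exists to separate sex from genotype.

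Of 16 marginal zone genes 2 were called, both lower, and 3 fold changes were positive (adjusted p = 0.276 for the list with an estimated correlation). Dilution by RNA of other cells would lower B cell genes alike. The BCR signaling median was -0.01, with a 95% bootstrap interval from -0.0267, against a marginal zone median of -0.18 (interval -0.50 to -0.05). Those intervals resample genes rather than arrays. Array means (deviations from the mean of all arrays, SD, n = 3) fell from 0.136 ± 0.0734 to -0.136 ± 0.0435 for marginal zone genes. For BCR signaling genes they were -0.000946 ± 0.0091 and 0.000946 ± 0.0031. RMA removes a fall shared by most transcripts, but that would move both lists alike. The gap argues against an equal dilution of all B cell genes as the only cause of the marginal zone fall. Whether other cells express the BCR list genes too was not tested, so a part of dilution stays open. Further, 7 of 7 follicular genes (median -0.08) and 9 of 10 germinal center genes (median -0.23) were negative, as dilution would give. A smaller share of marginal zone B cells could neither be shown nor excluded, since the list's mean pairwise correlation within groups was 0.0983: this met the bound set beforehand against such a change, the random median of 0.140, but lay well inside the spread of random lists (central 95% -0.0209 to 0.397). Sex of the mice may also contribute. On the scale from the other controls to the transgenic mean, control 3 lay at -16.2% for Dtx1 and -51.2% for Myof. These were the 2 called genes (median -33.7%), and 1 such array cannot decide whether sex contributes. An effect of the transgene or of Cre was not tested.

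Control 3 had Y-linked signal together with high Xist. The 3 Y-linked genes lay 33.4% to 42.1% of the way, with a median of 37.8%, from the other controls to the transgenic mean on the linear scale, consistent with cells of male and female mice in 1 sample. Transgenic RNA mixed into control 3 stays open. The 5 cluster probe sets lay a mean of -0.33 log2 units (95% interval -0.70 to 0.04) from the level that mixing at 33.4% would give. That interval measures the spread between 5 probe sets of 1 cluster in 1 array, not between samples, so it cannot decide. Mir18, Mir19b-1, Mir19a and Mir17 lay at -0.61, -0.61, -0.36 and -0.19, and Mir20a at 0.10. The positions of the 5 probe sets ranged from 5.03% for Mir18 to 42.4% for Mir20a. X genes known to escape inactivation were lower in 6 of 6 cases (median log2 fold change -0.32), with Kdm6a at -0.69 (limma adjusted p = 0.0114) and Eif2s3x at -0.58 (0.0284) called. Controls 1 and 2 had the pattern of female cells, with Xist at 10.82 and 10.21 and Eif2s3y at 3.70 and 3.96. All 3 transgenic arrays had that of male cells, with Xist at 4.60 to 6.07 and Eif2s3y at 9.07 to 9.48. Sex was read from transcripts only. With such a difference, sex and genotype cannot be told apart in this comparison.

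Control 1 and transgenic 2 shared 145 probe sets over 2 log2 units higher than in the other 4 arrays, 98 of them unnamed, with a median difference of 2.57. Of the 19938 genes compared, by contrast, 5 had a mean over 1 log2 unit higher and 1 a mean over 1 log2 unit lower in that pair than in the other 4 arrays.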
